A study of Mus musculus with 8 samples.

How the data were processed

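Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and inserts sequencing adapters, in bone marrow-derived macrophages of wild-type (WT) and Nfat5 knockout (KO) mice. Per the labels, bone marrow cells were cultured for 7 days with 25% conditioned medium of a fibroblast line that secretes the macrophage growth factor M-CSF. They were then left untreated or treated with 0.3 ng/ml lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria) for 2 h. The 8 libraries form 4 groups of 2. The labels carry codes shared by an untreated and an LPS library of a genotype, but do not state whether these came from the same animal.

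The deposited unit was a list of peak positions for each library, which the authors made by calling peaks in each library separately, 1 list per library, per the labels. Each deposited list gave the chromosome, start and end of every peak on build GRCm38 (mm10) and no score, height, fold enrichment, count or p-value. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Bowtie2 2.3.0, Picard and MACS2 2.1.1 were used. The role and settings of each tool, the calling threshold, the treatment of duplicate reads and any shift of the cut sites are not given in the sources used here. These steps set which weak peaks enter a list. The depth of each library is therefore unknown, no counting interval could be given, and a region missing from a list was not called there, which does not show that it was closed. The narrowest peak of each list was between 156 and 174 bases wide.

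Peaks of the 21 main chromosomes were merged across the 8 lists where they overlapped by at least 1 base. This gave 87260 consensus regions with a median width of 468 bases, covering 48.9 Mb. A library called a region when 1 of its peaks overlapped the region by at least 1 base. A region was gained with LPS when both LPS libraries and neither untreated library of a genotype called it, and lost in the reverse case. WT-only and KO-only regions were defined in the same way between genotypes within a treatment. Each count was set beside the counts of the 4 other ways in which exactly 2 of the 4 libraries can call a region. A comparison of 2 libraries against 2 has 3 splits and a smallest p of 0.333, so these counts have no p-value. Over all 8 libraries, regions called in all 4 libraries of one arm and none of the other were counted for each of the 35 splits into 4 and 4.

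Library values (number of peaks, covered sequence, median width and location shares) were compared 4 against 4 with a two-sided exact permutation test over 70 arrangements, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 26 tests. Regions were assigned to the nearest of 21887 protein-coding genes of the GRCm38.p6 gene table within 100 kb of the gene body. The table gives gene bodies without strand, exons or transcription start sites, so a region within 1 kb of either end of a gene was called near a gene end, in place of the planned promoter share. Start positions are given counting from 1.

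Gene lists (19 lists with 342 entries, of which 4 had no match in the gene table) covered early and late LPS response genes, interferon response genes, LPS genes linked to NFAT5, osmotic stress genes, MHC class II, macrophage identity, alternative activation, chemokine and homing receptors, cholesterol and lipid handling, cell cycle, housekeeping genes, and markers of 7 other cell types (T cell, B cell, neutrophil, dendritic cell, erythroid, fibroblast or stroma, mast cell or basophil). The share of regions assigned to a list was compared by a two-sided Fisher's exact test with the other regions called in exactly 2 of the same 4 libraries. These hold the regions of the opposite direction, so a low odds ratio in one direction can follow from a high one in the other. Odds ratios have 0.5 added to each cell and a 95% interval, and p was adjusted over the 38 tests of a comparison (19 lists and both directions). The share of each library's peaks assigned to each list was compared by the exact permutation test.

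The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 regions per comparison and direction with the highest mean rank by peak width within their lists, 1 region per gene, up to 4 genes per list and direction by the same rank, and Nfat5, Ciita, Il6, Il12b, Nos2, Tnf, Il1b, Ptgs2, Ccl2 and Cxcl10 in any case. Predicted genes were named only where too few others remained, and a few regions that the rule selects are not reported here. Peak width took the place of a peak score, which the lists do not hold, in the rank and in the alternatives with equal list lengths (the widest 54027 peaks of each list) and with stricter lists (the widest 27013). These width alternatives, the distance to the nearest gene end and tests counted by gene were chosen after seeing the data. Further alternatives were coverage of at least 50% of a region, bins of 500 bases, autosomes only, and other gene windows and backgrounds. Each library was also left out in turn. Sign changes were made within pairs of the same replicate number, which also shared genotype (for LPS) or treatment (for WT against KO). The 12 transcription factor motifs chosen for testing were not analysed here, because that needs the genome sequence.

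The counting and list tests were tested on simulated data for LPS in WT with all 87260 regions. Calls were drawn independently per library from the call frequency of each region over all 8 libraries and the overall rate of the library, which gave 1605 to 1762 gained regions before planting. Of 200 planted regions, 100% were found in each of 20 simulations. They were planted with the calls that define a gained region, so this was fixed in advance. A planted list was called in 20 of 20, and 1 of 80 tests without a planted effect was called. Each simulated region had a gene of its own, so these tests do not cover regions that share a gene. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.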

Results

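NFAT5 is a transcription factor best known for its part in the response of cells to high salt, and it also takes part in macrophage responses to bacterial products. Accessible chromatin was mapped by ATAC-seq in macrophages grown from the bone marrow of WT and Nfat5 KO mice, either untreated or after 2 h with 0.3 ng/ml LPS, with 2 libraries per group. The deposited peak lists held 60117 and 59218 peaks in untreated WT, 57691 and 55506 in WT with LPS, 56346 and 59811 in untreated KO, and 54911 and 54027 in KO with LPS. Sequencing depth is unknown. Of the 87260 consensus regions, 36009 (41.3%) were called in all 8 libraries and 17564 in a single library. Libraries of the same group shared 74.8% of their regions on average (73.3% to 75.6%). Libraries of the same treatment and other genotype shared 72.5%, with 73.3% to 74.6% untreated and 70.6% to 71.4% with LPS. Libraries of the same genotype and other treatment shared 68.4%, and libraries that differed in both 67.0%. Nothing in the labels states that replicates came from separate cultures, so the exact permutation p-values measure the spread between these samples only. Fisher's exact p-values count regions and hold no spread between libraries. Regions are not independent replicates of one another, so a small value of that test does not show that a difference would recur in other samples.

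The targeted gene, Nfat5 (chromosome 8, 107293435 to 107379517, GRCm38), was the nearest gene of 7 regions within 100 kb. Of these, 4 were called in all 8 libraries. These included the region over 1 end of the gene (107292751 to 107293816), with peaks of 454 to 1066 bases. A region inside the gene (107329619 to 107329854) was called in both untreated KO libraries and KO LPS library 2 and in no WT library. Another region within 100 kb was assigned to Wwp2, inside which it lies (107449294 to 107449951). It was called in all WT libraries and in no KO library. The part of the gene deleted in the KO is not given in the sources used here, so these peaks check nothing about the deletion.

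Called peaks were narrower with LPS and covered less sequence. The 4 LPS libraries covered 27.3 ± 0.770 Mb (SD, n = 4) and the 4 untreated libraries 30.5 ± 0.703 Mb, with all LPS libraries below all untreated ones (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.186 over 26 tests). The median peak width was 407.5 ± 6.14 bases against 434 ± 8.83 (exact permutation p = 0.0286, adjusted p = 0.186, n = 4). The number of peaks was 55534 ± 1561 against 58873 ± 1726 (exact permutation p = 0.0571, adjusted p = 0.248, n = 4). None of the 3 differences passed the adjustment. With a smallest p of 0.0286 over 26 tests, a measure that separated the arms completely could not pass on its own. WT and KO libraries covered 29.4 ± 1.85 and 28.3 ± 1.96 Mb (exact permutation p = 0.457, n = 4). Within each treatment both WT libraries covered more than both KO ones, with at least 30.9 Mb in WT and at most 30.4 Mb in KO untreated, and at least 27.7 and at most 27.1 Mb with LPS.

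The first comparison asked which regions were gained or lost with LPS in WT macrophages. Among the widest regions called in both WT LPS libraries and in neither untreated one were regions at Clec4e, a receptor for mycobacterial glycolipid (chromosome 6, 123279795 to 123281794, overlapping the gene, mean peak width 1497 ± 604 bases, SD, n = 2). Others lay at Nfkbiz, a nuclear regulator of NF-kB (chromosome 16, 55809226 to 55810766, outside the gene and 0.608 kb from it, 1313 ± 35.4 bases), and at Zc3h12c, an RNase of immune cells (chromosome 9, 52106588 to 52108618, outside the gene, 1327 ± 301 bases). The remaining regions of this rank lay at Klhdc4, Insig2, Mageb5, Ppargc1b, Ak5, Ifit1 and Metap1. Of these, the Ifit1 region (chromosome 19, 34649914 to 34651400, overlapping this interferon-induced antiviral gene) had peaks of 1254 and 942 bases with LPS.

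Of the 40 early LPS response genes, 13 had gained regions only, 5 lost regions only, 6 both and 16 neither. Gained regions lay near Tnfaip3, an inhibitor of NF-kB signalling (chromosome 10, 19077699 to 19078553, 62.3 kb from the gene, 838.5 ± 23.3 bases, n = 2), and inside Nfkb1, which encodes an NF-kB subunit (chromosome 3, 135670429 to 135671218, 752.5 ± 13.4 bases). The list had 43 gained regions among 3454, against 17 of 8220 other regions called in exactly 2 of these libraries (odds ratio 5.98, 95% interval 3.43 to 10.4, two-sided Fisher's exact p = 1.88e-11, adjusted p = 7.16e-10 over 38 tests). Late LPS response genes had 20 gained regions (odds ratio 5.16, 2.39 to 11.1, exact p = 1.33e-05, adjusted p = 0.000253), and 12 of the 22 genes with a region gained at least 1. They included Il12a, a subunit of a cytokine that activates T cells (chromosome 3, 68693084 to 68694038, inside the gene). Others were Ptges, which makes prostaglandin E (chromosome 2, 30927164 to 30927662, inside the gene), Edn1 and Lif. Interferon response genes had 16 gained regions (odds ratio 3.75, 1.73 to 8.14, exact p = 0.000817, adjusted p = 0.0104), at 12 of 31 genes. The region over Ifnb1, the gene of interferon beta (chromosome 4, 88522641 to 88523555), had peaks of 903 and 761 bases with LPS. That over Rsad2, an antiviral enzyme (chromosome 12, 26441764 to 26442861), had 1098 and 452. LPS genes linked to NFAT5 had 9 gained regions (odds ratio 5.03, 1.64 to 15.5, exact p = 0.00361, adjusted p = 0.0343). They lay at 7 of 11 genes, among them Tnf, Traf1, Ccl2 and Il12b, and 10 of the 11 genes also stand on the early or late list.

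The other 15 lists did not pass among gained regions (adjusted exact p from 0.185 to 1). Odds ratios were 7.15 for MHC class II (4 regions, at H2-Ob, Ciita and Cd74), 1.95 for osmotic stress and 1.48 for macrophage identity (11 regions, at Tlr4, Axl, Siglec1 and others). They were 0.793 for alternative activation, 1.54 for chemokine and homing receptors, 1.93 for cholesterol and lipid handling, 0.793 for cell cycle and 0.549 for housekeeping genes. Markers of other cell types had 0 to 5 gained regions per list. Their odds ratios were 1.70 for T cells, 0.793 for B cells, 0.915 for neutrophils and 1.25 for dendritic cells. They were 7.14 for erythroid cells (1 region), 2.38 for fibroblasts or stroma (5 regions, at Dcn, Pdgfrb and Cxcl12) and 0.476 for mast cells or basophils.

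The interferon call ended without WT untreated library 2 (odds ratio 2.09, adjusted exact p = 0.214) or WT LPS library 1 (2.27, adjusted p = 0.167). The call of genes linked to NFAT5 ended without WT LPS library 1 (odds ratio 3.42, adjusted exact p = 0.167) or 2 (3.22, adjusted p = 0.0714) and within 25 kb (6.20, adjusted p = 0.0994), and the late call ended within 25 kb (3.66, adjusted p = 0.0908). MHC class II passed among gained regions without WT untreated library 1 (odds ratio 21.0, adjusted exact p = 0.0206) or 2 (20.1, adjusted p = 0.0308).

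In all, 3454 regions were gained and 4414 lost in WT, against 778 to 1195 (mean 951.5) for the 4 other pairs of libraries. Calls simulated independently in each library, without a difference between groups, gave 1605 to 1762 gained regions in 20 simulations. Their call frequencies came from all 8 libraries, so regions that differ between groups entered as regions called at random. This simulated count is therefore not a clean level for no difference. The widest lost regions included those at Oprk1, Ppp2r5c, Pcdh1, Wdr75, Arap2, Gramd1a, Ramp3 and E2f2, of which that at Ppp2r5c did not count as lost in WT or KO when at least 50% of the region had to be covered. Lost regions of the early list included one outside Nfkbia, which encodes an NF-kB inhibitor, 0.195 kb away (chromosome 12, 55488588 to 55489213), and one over Il10, an anti-inflammatory cytokine (chromosome 1, 131019493 to 131020036). Another lay over Ccl4, a chemokine (chromosome 11, 83663428 to 83663922). No list passed among lost regions. The early list had 13 lost regions (odds ratio 0.466, adjusted exact p = 0.0808), with its 43 gained regions in the background. Macrophage identity had 14 (odds ratio 1.54, adjusted exact p = 0.798, at Cd36, Adgre1, Mertk, Maf and others) and alternative activation 7 (1.18, adjusted p = 1, at Klf4, Tgm2, Pparg and others). Which direction was larger differed between alternatives. The ratio of lost to gained regions was 1.28 as deposited, 0.870 at equal list length by peak width (3289 lost, 3781 gained) and 0.889 without WT LPS library 2. Leaving out any 1 of the 4 libraries raised the counts, to between 4886 and 7510 gained and 6674 and 9910 lost, since 1 arm then holds a single library.

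**Figure D1:**
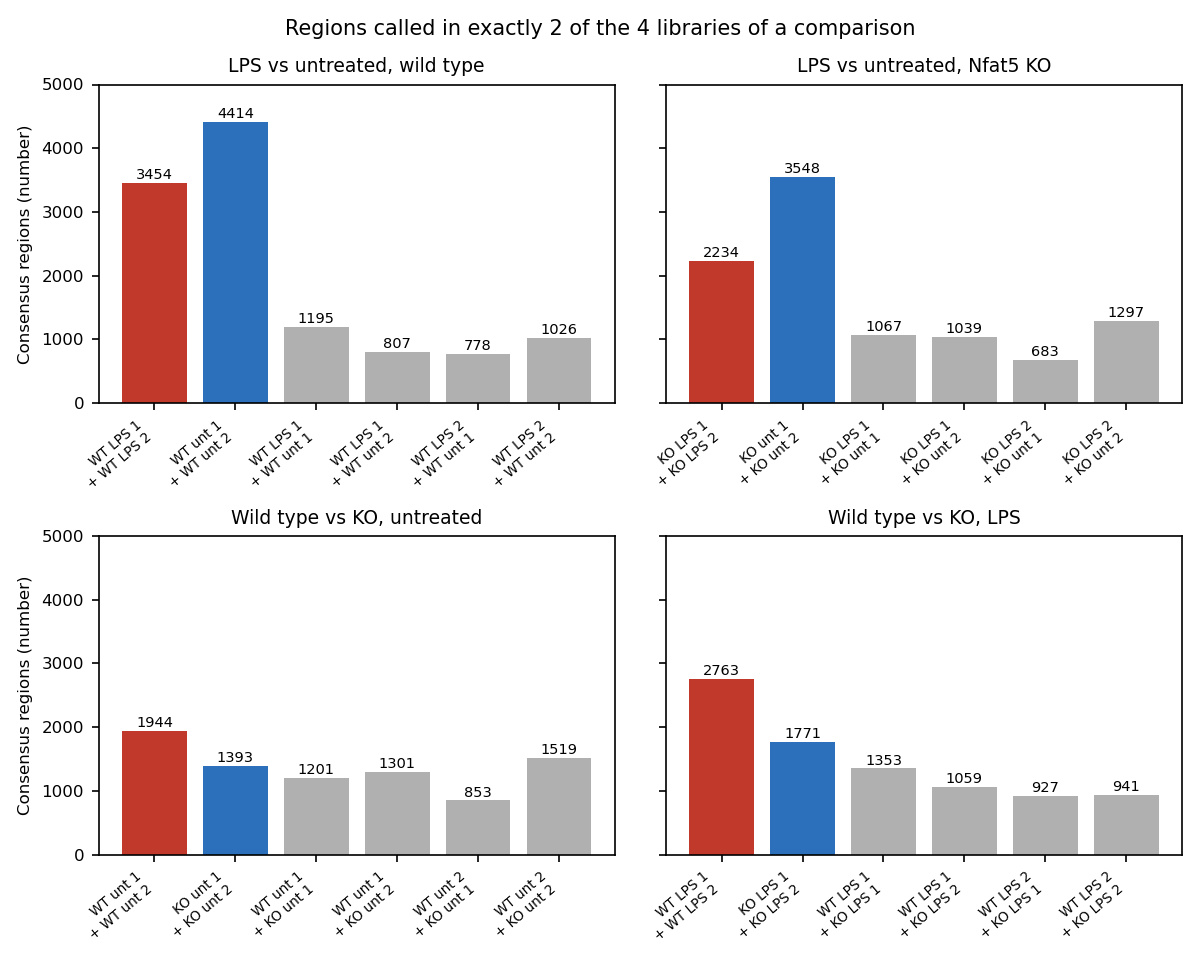
Number of consensus regions called in exactly 2 of the 4 libraries of each comparison (vertical axis, regions). In each panel the red and blue bars are regions called in both libraries of one group and neither of the other, and the grey bars are the 4 other pairs of libraries; with LPS in WT the 2 coloured bars stand at 3454 and 4414 and the grey bars between 778 and 1195.

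The same comparison in KO macrophages gave gained regions at several of the same genes. The Clec4e region had peaks of 1310 and 1206 bases in the KO LPS libraries and the Zc3h12c region 1756 and 859, although the latter did not count as gained when at least 50% of the region had to be covered. Map2k6, a kinase that activates stress-responsive MAP kinases, had a gained region inside the gene (chromosome 11, 110429711 to 110430856, 1140 ± 8.49 bases, n = 2). Cxcl15, Ptprt, Lcp1, Fgd2, Slco3a1, Btg1 and Rassf4 completed the widest. At each of these 7 the region was also called in at least 1 untreated WT library.

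Of the 40 early LPS response genes, 12 had gained regions only in KO, 7 lost regions only, 3 both and 18 neither. The list had 20 gained regions of 2234, against 16 of 7634 (odds ratio 4.27, 2.23 to 8.19, Fisher's exact p = 1.85e-05, adjusted p = 0.000506 over 38 tests), with Nfkbiz, Tnf and Tnfaip3 among them. Late LPS response genes had 13 (odds ratio 7.13, 2.79 to 18.2, exact p = 2.66e-05, adjusted p = 0.000506), at 8 of 21 genes, with Il12a, Ptges, Il12b and Nos2 among them. Genes linked to NFAT5 had 8 (odds ratio 11.7, 2.84 to 47.8, exact p = 0.000197, adjusted p = 0.00249), at Il12b, Nos2, Tnf and Traf1. Interferon response genes had 7 (odds ratio 1.77, 0.732 to 4.28, exact p = 0.293, adjusted p = 0.934), at Ccl5, Usp18, Gbp3, Cmpk2, Socs3 and Isg15. Lists of other cell types had 0 to 5 gained regions, and the fibroblast or stroma list came nearest to the threshold (5 regions, at Dcn, Fap, Pdgfrb and Prrx1, odds ratio 7.53, exact p = 0.00821, adjusted p = 0.0780). Alternative activation had 7 (odds ratio 3.95, adjusted exact p = 0.107) and macrophage identity 10 (2.48, adjusted p = 0.218).

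All 3 calls ended without KO untreated library 1 (odds ratio 2.44 for the early, 3.70 for the late and 7.91 for the NFAT5-linked list, adjusted exact p = 0.0524 each), and the late call also ended without KO LPS library 1 (3.14, adjusted p = 0.0562). Within 25 kb the late list gave 4.05 (adjusted exact p = 0.203) and the NFAT5-linked list 7.53 (adjusted p = 0.136), and counted by gene the latter gave 7.57 (adjusted p = 0.191).

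In KO, 2234 regions were gained and 3548 lost, against 683 to 1297 (mean 1021.5) for the other pairs. The widest lost regions lay at Ppp2r5c, Ccdc152, Asmt, Cdkal1, Tnrc6a, Atp23, Fbxw7, Trim47, Slc38a9 and Sdk2. Lost regions of the fixed lists included one inside Tnf (chromosome 17, 35200384 to 35201213) and one over Ccl4. Others lay inside Ifih1, a sensor of viral RNA (chromosome 2, 62627936 to 62628189), and inside Spi1, the gene of the myeloid transcription factor PU.1 (chromosome 2, 91097976 to 91098479). No list passed among lost regions. The ratio of lost to gained regions was 1.59 as deposited, 0.927 at equal list length by peak width (2540 lost, 2741 gained), 1.01 without KO LPS library 2 and 2.78 without KO untreated library 1. Leaving out any 1 of the 4 libraries gave 3326 to 6088 gained and 6178 to 9248 lost regions, again with a single library in 1 arm.

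**Figure D2:**
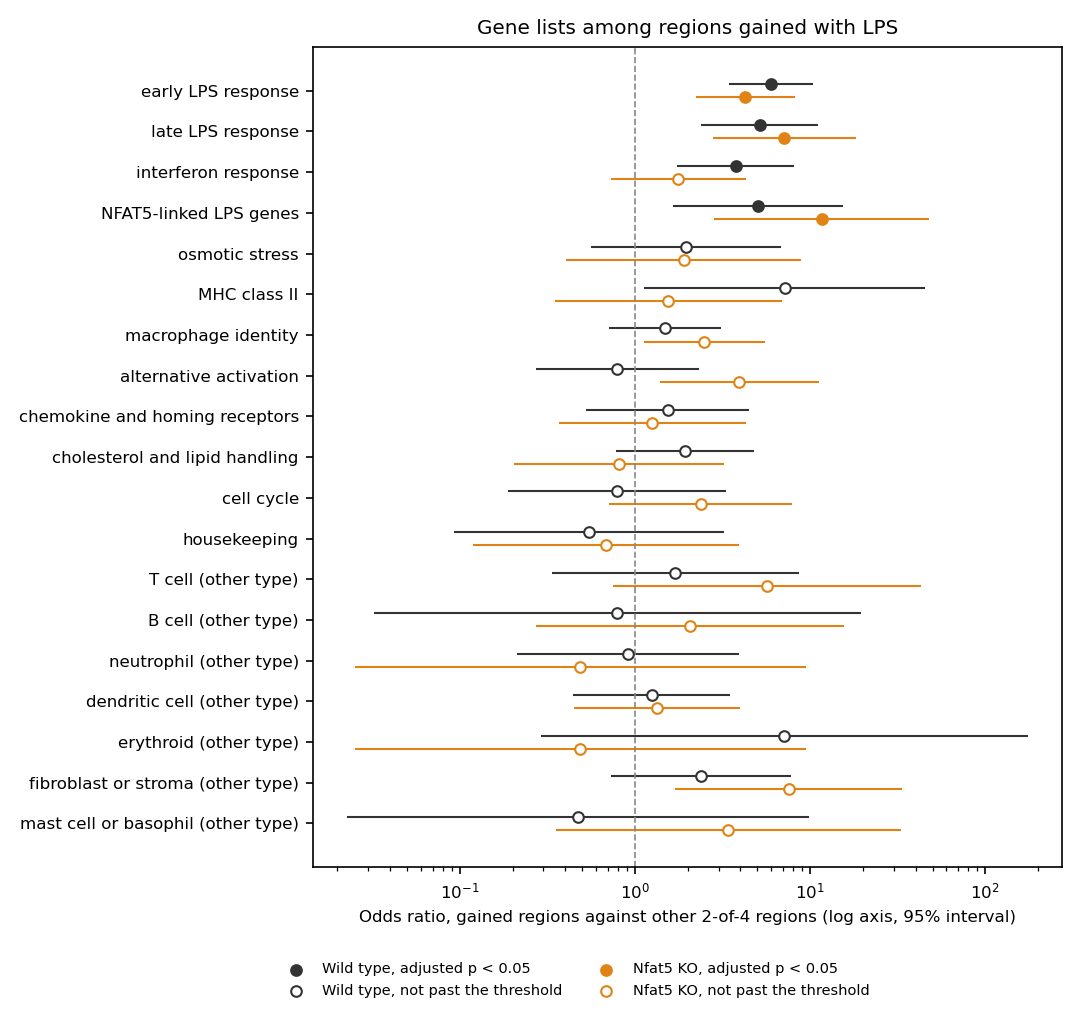
Odds ratio (horizontal log axis) with its 95% interval for each gene list (vertical axis) among regions gained with LPS, against the other regions called in exactly 2 of the same 4 libraries, in WT (black) and KO (orange); filled points have an adjusted p below 0.05. In WT 4 lists pass, led by the early LPS response list at 5.98, and in KO 3 lists pass.

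Over both genotypes, 959 regions were called in all 4 LPS libraries and no untreated one, and 810 in all 4 untreated libraries and no LPS one. The gained regions included those at Clec4e, Nfkbiz, Zc3h12c and Map2k6, and one at Tlr4, the LPS receptor (chromosome 4, 66837573 to 66838259, inside the gene). Others lay at Ciita, which controls MHC class II genes (chromosome 16, 10498184 to 10498544, inside the gene), and at Mki67, a proliferation marker (chromosome 7, 135696758 to 135697432, inside the gene). Il12b, a cytokine subunit, gained regions at 2 places outside the gene (chromosome 11, 44372400 to 44373431 and 44382147 to 44382549). The early list had 15 of the gained regions (odds ratio 7.18, 3.27 to 15.8, exact p = 1.85e-06, adjusted p = 7.04e-05), the NFAT5-linked list 5 (17.7, 2.90 to 108, p = 0.000775, adjusted p = 0.0147) and the late list 7 (4.83, 1.75 to 13.3, p = 0.00493, adjusted p = 0.0625). Regions lost in all 4 included those at Ppp2r5c (1455 ± 438 bases, SD, n = 4), Tecta, Fbxw7 and Ccl4, and one over Aurkb, a mitotic kinase (chromosome 11, 69045444 to 69046034). The ratio of lost to gained regions was 0.845 as deposited, 0.403 at equal list length by peak width (457 lost, 1134 gained), and 1.21 with at least 50% of a region covered. It was also above 1 without WT LPS library 1 (1.06), WT untreated library 2 (1.07) or KO untreated library 1 (1.2).

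The share of peaks at each list was measured in every library as well, in per mille. At early LPS response genes it was 4.34 ± 0.298 per mille of peaks with LPS and 3.55 ± 0.0316 without (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0776). All LPS libraries also lay above all untreated ones for late LPS response genes (1.82 ± 0.0942 against 1.47 ± 0.0518), interferon response genes (2.24 ± 0.194 against 1.98 ± 0.0606) and genes linked to NFAT5 (0.968 ± 0.0288 against 0.764 ± 0.0413). They did so for macrophage identity (2.95 ± 0.0413 against 2.85 ± 0.0175) and the fibroblast or stroma markers (0.504 ± 0.0344 against 0.424 ± 0.0413), and lay below for neutrophil markers (0.383 ± 0.0368 against 0.416 ± 0.00586). Each had the same exact permutation p of 0.0286 and adjusted p of 0.0776 over the 19 lists (n = 4). None of these passed the adjustment. The LPS lists held fewer peaks on average, so a share can rise without more peaks at a list. Among these lists, only the early, late and NFAT5-linked ones had more peaks in every LPS library than in every untreated one. Macrophage identity genes had 161 to 169 peaks with LPS and 162 to 172 without. Interferon response genes in KO had 116 and 113 with LPS and 114 and 116 without.

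The design also asks how far the response to LPS was shared by the genotypes. Of the 3454 regions gained in WT, 959 (27.8%) were gained in KO, where independent lists would share 88.4, and 27 were lost in KO, where independent lists would share 140. Of the regions lost in WT, 810 (18.4%) were lost in KO, against 179 for independent lists. These expected numbers count all 87260 regions. Regions called in all 8 libraries (36009) or in a single library (17564) are among them and cannot be gained or lost in both genotypes. The expected numbers are therefore low, and an excess over them does not measure how far the response was shared. Of the WT-gained regions, 1002 moved by 1 call in the same direction in KO and 1285 had as many KO calls with LPS as without. WT gained 1.55 times as many regions as KO, and 1.38 times as many at equal list length by peak width. Sets that mixed WT and KO libraries gained 2044 to 2879 regions (2679 to 3127 at equal list length), so the KO count of 2234 (2741) lay within their range and the WT count above it. Regions called in both WT LPS libraries and in no other library numbered 998, and those called in both KO LPS libraries alone 209 (328 at equal list length). Pairs made of a WT and a KO LPS library had 145 to 352.

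Among regions gained in WT and called in no KO library were ones inside Acod1, which makes itaconate (chromosome 14, 103053480 to 103054087), and near Atf3, a stress-induced transcription factor (chromosome 1, 191167377 to 191167798, outside the gene). Others lay 92.6 kb from Il6 (chromosome 5, 29920114 to 29920522), outside Il1b (chromosome 2, 129387771 to 129388024 and 129410425 to 129410634), over Rsad2 and near Edn1. Acod1 and Edn1 had other regions that were gained in KO. At Nos2, which makes nitric oxide, regions outside the gene (chromosome 11, 78886849 to 78887454) and over a gene end (78920461 to 78920887) were called in all 4 LPS libraries and, untreated, in WT library 2 alone. Cxcl10, a chemokine, had 1 region, called in all 8 libraries, and Ptgs2 and Ccl2 each had 6 such regions. Set directly against each other, regions gained in WT and not KO held 28 early LPS response regions of 2495, and regions gained in KO and not WT 5 of 1275 (odds ratio 2.67, 1.07 to 6.66, exact p = 0.0253, adjusted p = 0.904). No list differed between the genotypes after adjustment.

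**Figure D3:**
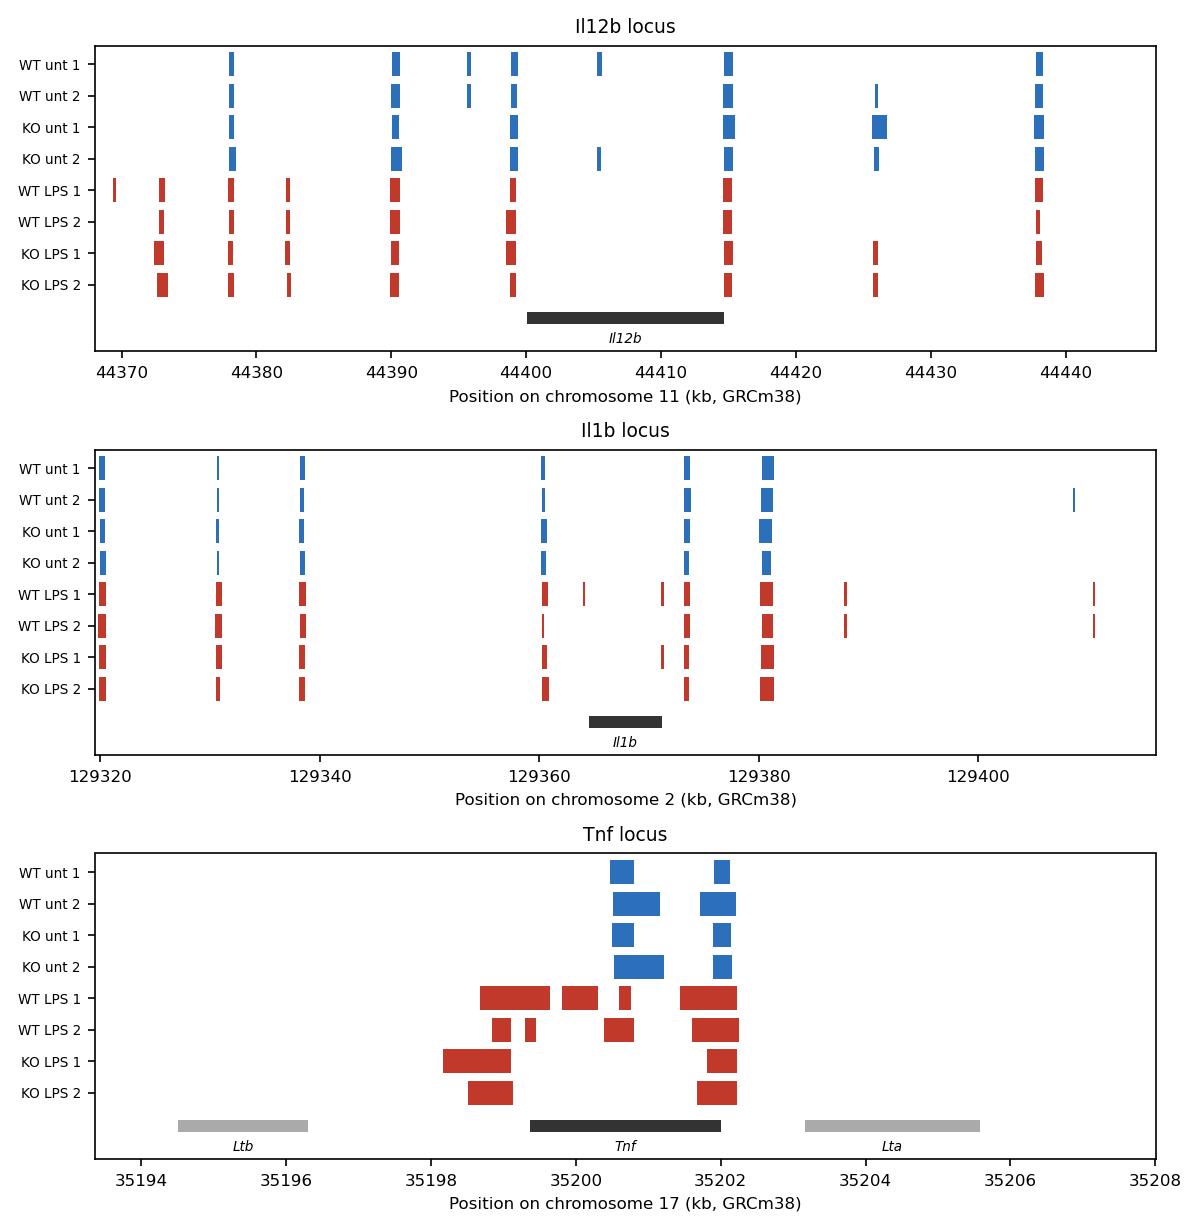
Called peaks (bars) of the 8 libraries (vertical axis, untreated blue, LPS red) at the Il12b, Il1b and Tnf loci, with gene bodies below (horizontal axis, position in kb on GRCm38). At Il12b the regions starting at 44372400 and 44382147 carry peaks in all 4 LPS libraries, at Il1b the 2 regions starting at 129387771 and 129410425 carry peaks in the WT LPS libraries alone, and at Tnf the region starting at 35200384 lacks a peak in both KO LPS libraries.

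Without treatment, WT-only regions numbered 1944 and KO-only regions 1393, against 853 to 1519 (mean 1218.5) for the other pairs, so the KO-only count lay within the range of pairs that mix the genotypes. The widest WT-only regions lay at Mief1, Adamts1, Trim2, Usp48, Prex1, Slco4a1, Nsmce2, Fmn1, Jak3 and Auts2. That at Jak3, a cytokine receptor kinase, overlapped the gene near its end (chromosome 8, 71676472 to 71677433, 753.5 ± 209 bases, n = 2). The widest KO-only regions lay at Kcnab1, Ryr2, Zfp950, Mageb5, Cdkl4, Olfr1223, Aig1, Fzd7, Col6a6 and Kcnh8. With at least 50% of a region covered, the Nsmce2, Mageb5 and Aig1 regions did not count. Among osmotic stress genes, 4 had WT-only regions. They were Slc5a3, a myo-inositol transporter (chromosome 16, 92037971 to 92038270, outside the gene), Slc6a12, a betaine transporter (chromosome 6, 121343196 to 121343435, overlapping the gene), Sgk1 and Akr1b3, and the KO-only region of this list lay inside Nfat5. No list passed in either direction (osmotic stress WT-only odds ratio 3.23, 0.873 to 11.9, exact p = 0.0962, adjusted p = 1, and NFAT5-linked 4.52, 0.891 to 22.9, p = 0.0900, adjusted p = 1). Among WT-only regions the largest count was 5 for macrophage identity, with regions at C1qb, Fcgr1 and Msr1 among them, and among KO-only regions 3 for cholesterol and lipid handling, at Abca1, Abcg1 and Insig1, and 3 for the late list. Lists of other cell types had 0 to 3 WT-only and 0 to 2 KO-only regions. At equal list length by peak width there were 1583 WT-only and 1628 KO-only regions, and the ratio of KO-only to WT-only regions of 0.717 became 1.03, or 1.55 without KO untreated library 1. Leaving out any 1 of the 4 libraries gave 3646 to 6388 WT-only and 3103 to 5640 KO-only regions.

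With LPS, WT-only regions numbered 2763 and KO-only regions 1771, against 927 to 1353 (mean 1070) for the other pairs. The widest WT-only regions lay at Thada, Osbpl1a, Syne1, Auts2, Ptprt, Cldn14, Uaca, Cbln4, Saxo1 and Riiad1, and the widest KO-only regions at Ids, Zfp950, Ryr2, Pcdh1, Klhl14, Olfr1223, Mzt1, Kcnab1, Tox and Cdh10. With at least 50% of a region covered, the Syne1, Mzt1, Kcnab1 and Tox regions did not count. Of the 40 early LPS response genes, 8 had WT-only regions, 1 KO-only regions, 3 both and 28 neither. The WT-only regions included those at Acod1, Atf3 and Irak3, an inhibitor of Toll-like receptor signalling (chromosome 10, 120177261 to 120177681, inside the gene). Acod1 and Irak3 had other regions that were gained in KO. The KO-only regions included those at Nfkbia and Il10, which were also called in all untreated libraries. The region inside Tnf (35200384 to 35201213) was called in both WT LPS libraries, with peaks of 172 and 415 bases, and in neither KO one. MHC class II genes had 6 WT-only regions, at H2-Ob (chromosome 17, 34249781 to 34250459, outside the gene), Ciita (chromosome 16, 10489242 to 10489712, inside the gene), H2-Eb1 and Cd74. Osmotic stress genes had 6, at Slc6a12, Hspa4l, Slc5a3, Slc6a6 and Sgk1.

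No list passed between genotypes with LPS, where 5 of the 19 lists had an unadjusted exact p below 0.05 among WT-only regions and 0 among KO-only regions. They included MHC class II (odds ratio 9.51, 1.61 to 56.2, exact p = 0.00484, adjusted p = 0.184) and osmotic stress (5.70, 1.33 to 24.5, p = 0.0142, adjusted p = 0.270). The others were alternative activation (0 regions, 0.0874, exact p = 0.0235, adjusted p = 0.292), cell cycle (3 regions, 15.3, p = 0.0308, adjusted p = 0.292) and the early list (17 regions, 1.97, 1.03 to 3.76, p = 0.0473, adjusted p = 0.360). Lists of other cell types had 0 to 4 WT-only and 0 to 2 KO-only regions. Single libraries changed this. Without WT LPS library 2 the early (odds ratio 3.56, adjusted exact p = 0.000213) and interferon lists (3.75, adjusted p = 0.00300) passed, without KO LPS library 1 the early list (2.88, adjusted p = 0.0476), and without KO LPS library 2 MHC class II (23.7, adjusted p = 0.0202). The share of peaks at MHC class II genes was 0.431 ± 0.0533 per mille in WT and 0.356 ± 0.0256 in KO (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.407). The ratio of KO-only to WT-only regions was 0.641 as deposited, 0.945 at equal list length by peak width (2104 and 2226), 1.03 without KO LPS library 1, 1.18 without KO LPS library 2 and 0.420 without WT LPS library 2. Leaving out any 1 of the 4 libraries gave 4841 to 7292 WT-only and 3066 to 5716 KO-only regions. The arm of the library left out then needs a single call, which shifts the ratio toward that arm by construction.

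Over both treatments, 202 regions were called in all 4 WT libraries and no KO library, and 128 in all 4 KO libraries and no WT library. The widest WT-only regions lay inside Rbpms, Riiad1, Ptpn13, Wdfy4 and Dlg2, over an end of Zfp781 and near Mapk6. Others lay 23.0 kb from Vcan, which encodes an extracellular matrix proteoglycan (chromosome 13, 89766057 to 89766835, 619.5 ± 215 bases, SD, n = 4), 1.1 kb from C1qb, a complement gene (chromosome 4, 136878227 to 136878990, 512 ± 145 bases), and inside Wwp2 (chromosome 8, 107449294 to 107449951), a gene close to Nfat5. The widest KO-only regions lay inside Ryr2 (chromosome 13, 12027526 to 12028590, 932 ± 93.4 bases), Kcnab1 (chromosome 3, 65195426 to 65197378), Kcnh8, Pigf and Rara, over an end of Kcnk12, and outside Zfp950, Olfr1223, Cdh10 and Olfr1214. No gene list passed in either direction (smallest exact p = 0.0455, adjusted p = 0.903). At equal list length by peak width the counts were 146 WT-only and 179 KO-only, so the ratio of KO-only to WT-only regions went from 0.634 to 1.23. Leaving out WT LPS library 2 gave a KO-only to WT-only ratio of 0.428, with ratios up to 0.898 without the other libraries in turn.

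Regions near a gene end were scarcer among gained regions than among the other regions called in exactly 2 of the same libraries, at 5.76% against 7.96% in WT (odds ratio 0.708, two-sided Fisher's exact p = 2.51e-05, adjusted p = 5.02e-05 over 12 tests) and 6.0% against 9.48% in KO (0.611, p = 1.11e-07, adjusted p = 3.32e-07). Lost regions had 7.14% in WT (0.961, adjusted exact p = 0.608) and 9.64% in KO (1.2, adjusted p = 0.0222). Within 500 bases of a gene end they had 3.92% (0.809, adjusted exact p = 0.0455) and 6.57% (1.18, adjusted p = 0.0839), so which of these passed depended on the distance. With LPS, 11.1% of WT-only regions, such as that of H2-Eb1, and 5.19% of KO-only regions were near a gene end (odds ratio 2.26, 1.78 to 2.88, exact p = 2.55e-12, adjusted p = 3.06e-11), and without treatment 8.69% and 7.32% (1.2, 0.932 to 1.55, p = 0.158, adjusted p = 0.198). The share of all peaks near a gene end was 20.6 ± 0.420% in WT and 20.6 ± 0.398% in KO libraries (SD, n = 4, exact permutation p = 1).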

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

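The alternatives by peak width, the tests counted by gene and the distance to the nearest gene end were chosen after seeing the data, and all others before. Of the main values set against an alternative, 185 kept their direction and stayed within 1.5 times, or for p-values stayed on the same side of 0.05, 85 moved further, 20 turned round and 2 became weaker. Among the other values 280 stayed and 31 became weaker. The deposited lists hold no depth and no score, so a region missing from a list may have been missed there, and the comparisons by peak score and the motif tests with both of their variants, chosen before the data were examined, were not run.

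At equal list length by peak width some counts rose and others fell. With the widest 27013 peaks of each list, 1946 regions were gained and 1683 lost in WT (ratio of lost to gained 0.865), 1383 were lost in KO (ratio 0.879), 892 were WT-only without treatment (ratio of KO-only to WT-only 1.07), and 1246 were WT-only and 1179 KO-only with LPS. Over both genotypes 536 were gained and 241 lost (ratio 0.450), and over both treatments 94 were WT-only (ratio 1.03). With regions called by those widest peaks and absence judged by the full lists, which can only lower a count, 388 were gained and 186 lost in WT (ratio 0.479), and 250 gained and 107 lost in KO (ratio 0.428). The same rule gave 58 WT-only and 47 KO-only regions without treatment, and 112 WT-only and 109 KO-only with LPS (ratio 0.973). It left 83 regions gained and 10 lost in both genotypes (ratio 0.12), and 3 WT-only and 10 KO-only in both treatments (ratio 3.33).

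At equal list length by peak width the ratio of lost to gained regions was 0.870 in WT, 0.927 in KO and 0.403 over both genotypes, where 457 regions were lost in both. The ratio of KO-only to WT-only regions was 1.03 without treatment and 1.23 over both treatments, and 328 regions were called in both KO LPS libraries alone. With at least 50% of a region covered the ratio of lost to gained regions over both genotypes was 1.21, and in bins of 500 bases 1.16. The cause of these turns was not tested. Each ratio between the directions of a comparison lay above 1 under some choices and below 1 under others. Between genotypes with LPS, the only ratios above 1 came from leaving out a KO LPS library (1.03 and 1.18). That setting favours KO-only regions by construction, so it does not show an unstable direction. Within 25 kb, 2 gene lists passed among gained regions in WT and 1 in KO, with fewer regions assigned. Of the 80 regions ranked highest by width, 70 kept their call with at least 50% covered.

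Leaving out each library in turn raised the counts between 2 and 2 libraries by construction, since 1 arm then needs a single library. For the same reason it shifted these ratios toward the arm of the library left out. Gained regions ranged from 4886 to 7510 in WT and 3326 to 6088 in KO, and lost regions from 6674 to 9910 and 6178 to 9248. WT-only regions ranged from 3646 to 6388 without treatment and 4841 to 7292 with LPS, and KO-only regions from 3103 to 5640 and 3066 to 5716. Over both genotypes gained regions ranged from 1028 to 1437 and lost regions from 1038 to 1272, and over both treatments WT-only regions from 281 to 386 and KO-only regions from 157 to 273. The ratio of lost to gained regions ranged from 0.889 to 1.90 in WT, 1.01 to 2.78 in KO and 0.874 to 1.2 over both genotypes. The ratio of KO-only to WT-only regions ranged from 0.486 to 1.55 without treatment, 0.420 to 1.18 with LPS and 0.428 to 0.898 over both. Lists past the threshold numbered 2 to 5 among gained regions in WT, 0 to 3 in KO and 0 to 2 among WT-only regions with LPS.

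The groups share replicate numbers. Over all regions, deviations of libraries of the same number had correlations of 0.0113 to 0.0423 between groups, and on autosomes of 0.0084 to 0.0377. The labels do not state shared animals, so the numbers were not taken as pairs in the main tests. On chromosomes X and Y, libraries numbered 1 lay apart from those numbered 2, with 1703 to 1763 against 1497 to 1601 peaks on X and 33 to 43 against 59 to 96 on Y, so a shared source or batch stays open. As an alternative, signs were changed within pairs of the same replicate number and genotype. The exact p of covered sequence and of median width with LPS then went from 0.0286 to 0.13, the smallest that 16 sign changes can give. Between WT and KO the pairs had the same number and treatment. The exact p of covered sequence went from 0.457 to 0.13, with WT above KO in 4 of 4 pairs. These pairs hold treatment fixed as well, so the lower p cannot be credited to the replicate number.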

Other observations

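Chosen only after the result was seen were the genes with several regions, all tests of regions without a gene within 100 kb, those of windows and clustering, the ratio of 1.24, and the counts by split and on chromosomes X and Y. Some genes drew several gained regions at once. In WT, Lpp, which encodes an adhesion protein, gained 13 of its 64 regions, Nfkb1 8 of 34, Hivep3 8 of 37, Etv6 7 of 40, and Ripk2, a kinase of bacterial sensing, 6 of 25. In KO, Lpp gained 5, and Cers6, a ceramide synthase, and Zbtb20, a transcriptional repressor, 6 each. In WT, Plcb1, a phospholipase, lost 8 of 47 regions, and in KO Itgb5, an integrin subunit, lost 5 of 14. Called in all 4 LPS libraries and no untreated one were 4 regions of Ikzf1, a regulator of blood cells, and 3 of the 6 of Plscr1, an interferon-induced gene. Lost in all 4 were 2 of 6 regions of Ccr2, a monocyte chemokine receptor, and 2 of 8 of Cd163, a scavenger receptor. KO-only regions in both treatments included 4 of 17 at Sgcd, a sarcoglycan, 3 of 13 at Cdh10, a cadherin, and 3 of 8 at Ryr2, a calcium channel.

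KO-only regions more often had no protein-coding gene within 100 kb, at 14.7% against 7.87% of WT-only regions without treatment, 18.9% against 7.85% with LPS and 24.2% against 3.47% over both (Fisher's exact odds ratios 2.02, 2.73 and 8.42, adjusted p = 7.19e-10, 1.88e-27 and 1.45e-08). Over all peaks the gap was smaller, at 8.37 ± 0.328% in KO and 7.49 ± 0.148% in WT libraries (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.186). Weak peaks of the KO libraries may explain part of this, since regions called in a single library had no gene nearby in 22.4 ± 5.12% in KO and 12.4 ± 1.57% in WT (SD, n = 4), a gap of 9.92 points (exact permutation p = 0.0286, adjusted p = 0.186). Their share near a gene end differed by -2.41 points (5.43 ± 1.39% and 7.84 ± 0.654%, exact permutation p = 0.0571), which cannot tell. For the share near a gene end, narrow peaks alone are not enough. With both treatments pooled, the comparison was made among regions called by the widest 27013 peaks of each list. There 15% of 167 WT-only and 3.42% of 146 KO-only regions lay near a gene end (odds ratio 4.60, Fisher's exact p = 0.000441). The lists hold no score and a wide peak can be weak, so this test cannot tell whether weak calls near the calling limit are enough. The share without a gene nearby was not tested among the widest peaks. A biological difference was not separated from library background.

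Fewer regions were gained with LPS in KO than in WT, with a ratio of 1.55 of WT to KO. Shorter KO lists stay open as a part of it, since at equal list length by peak width the ratio was 1.38, and with the widest 27013 peaks of each list it was 1.24 (1946 and 1573 regions). Single pairs of 1 LPS and 1 untreated library gave 8357 to 10137 regions called only with LPS in WT (mean 9382) and 7089 to 8602 in KO (mean 8006), a ratio of 1.17. A lower agreement of the KO replicates could therefore make up part of the gap, and this test cannot tell how much.

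Regions differing between genotypes in both treatments lay within 10 Mb of Nfat5 in 7 of 330 cases, against 26 of 5235 other regions called in exactly 4 libraries (odds ratio 4.56, 2.01 to 10.3, Fisher's exact p = 0.00271), as a segment of another strain carried along with the deleted gene would give. They lay inside Cdh5, Tango6, Wwp2, Zfhx3 and Phlpp2. Within 2 Mb 5 of 14 such regions differed, and in windows of 20 Mb that of Nfat5 had 20%, but windows on chromosomes 15 and 2 had 24.0% and 20.7%, with a median of 4.96%. Blocks of another strain elsewhere could add to this. The test used 124 of the 128 KO-only and 192 of the 202 WT-only regions, and random regions called in exactly 4 libraries. Of KO-only regions, 31.5% had another within 1 Mb, against 12.6 ± 4.04% of random regions. The ratio was 2.49 (permutation p = 0.0001, the smallest the draws can give, adjusted p = 0.0006). WT-only regions had 22.9% against 18.9 ± 3.77% (ratio 1.21, permutation p = 0.162, not past the threshold). Regions of 1 replicate number alone also clustered (ratios 2.37 and 3.10, adjusted permutation p = 0.0291 each), so clustering cannot tell.

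Of the 35 splits of the libraries into 4 and 4, treatment gave the most regions (1769, highest other split 330), so 1 split reached its count. Genotype gave 330, and 2 splits reached it, genotype itself and treatment, with 235 as the next highest count. Libraries numbered 1 had 1703 to 1763 peaks on chromosome X and 33 to 43 on Y, and libraries numbered 2 had 1497 to 1601 and 59 to 96.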
